A study of Mus musculus with 6 samples.

How the data were processed

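Poly(A)-selected RNA of mouse liver was sequenced in 6 libraries, 3 of mice on normal chow (control) and 3 of mice on chow containing polypropylene black microplastic (PB-MP). Per the labels' protocols, mRNA was isolated on poly(A) beads and the libraries were built with a directional kit. The submitters' processing notes name bcl2fastq and the genome build GRCm39, without their roles. The aligner, the counting program, the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The authors deposited raw read counts per gene symbol, without normalization, as whole numbers for 56674 rows, once per sample and once as a table of all 6 samples. The 6 columns of that table were identical to the single files. Of the rows, 939 share a name with another row (67 names, mostly small RNA families), and these held 0.0308% of the reads. The row with most reads kept the name and the others were tested under the name with a row number. Reads of paralogs, nuclear copies of mitochondrial genes and overlapping or antisense genes cannot be told apart without the counting settings, so values of such genes are uncertain.

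Samples were grouped by diet from the labels, and PB-MP was compared with control. Library totals ran from 68357478 to 112566641 reads. Genes were kept by the edgeR function filterByExpr (minimum count 10, minimum total count 15), which left 17871 genes for testing and 38803 rows untested. Libraries were scaled by TMM, and genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 at a Benjamini-Hochberg adjusted p below 0.05 with no fold minimum. The SE of a log2 fold change is its size divided by the square root of F, and its 95% interval uses the t quantile of the fit. Metabolic genes were counted as bounded where this interval lay within -1 to 1. Fold changes are PB-MP over control. CPM values in the text are TMM-scaled, and log2 CPM for distances and principal components used a prior count of 2. Single values per library were compared by exact permutation over the 10 splits of 3 against 3 libraries, which cannot give a p below 0.1. No pair of libraries had counts that agreed within sampling noise, the chi-square per degree of freedom between 2 libraries being at least 196.

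Gene lists were tested with camera of limma 3.58.1 on voom values of the same genes, with a preset correlation of 0.01 and adjustment over the 44 lists with at least 3 tested members. Before the data were examined, 46 lists had been fixed, namely 11 of metabolism, 14 of stress and tissue responses, 6 of hepatocyte classes and 15 of cell type markers. The genes named in the text followed a rule fixed at the same time. It takes up to 12 genes per direction past the threshold with the largest fold changes, at a mean of at least 1 CPM and without overlap between groups, filled where fewer than 8 per direction pass with the genes of smallest p that meet the same limits, leaving out names that are only identifiers or predicted models. It adds per list up to 3 members past the threshold, filled to 2 by smallest p at a mean of at least 1 CPM (up to 2, filled to 1, for cell type markers), and 12 anchor genes whatever their result. Genes outside this rule are named because they passed adjusted over their list alone, or were chosen after their values were seen. Adjustment over a list alone takes no account of the number of lists.

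Alternatives fixed before the data were examined were other scalings, other filters, DESeq2 1.42.0, limma-voom with and without library quality weights, robust estimation, a replicate block, each library left out in turn, looser thresholds, and for lists an estimated correlation and fry. The alternatives chosen after seeing the data left out ribosomal RNA and mitochondrial rows, genes nearly lost in 1 library, or control replicate 2 and PB-MP replicate 3 together. The gene test was tested on simulated data with the real means, dispersions and library sizes (17380 genes passed the filter there). The 200 changed genes were drawn only from tested genes with a mean of at least 1 CPM. The gene test recovered 0 of 67 genes changed 1.5-fold, 2 of 67 changed 2-fold (2.99%) and 31 of 66 changed 4-fold (47.0%). It made 38 calls, 5 of them on unchanged genes. In a second simulation with no changed gene it made 0 calls, 4.45% of genes had an unadjusted p below 0.05, and the 95% interval covered 0 for 95.6% of genes. Of 2 gene lists shifted by a log2 of 0.5 in otherwise independent simulated genes, 2 were recovered and 0 other lists were called. Real genes are correlated, which the preset correlation may understate. The reference annotation used was GENCODE M21 on the assembly GRCm38, not the build GRCm39 named in the processing notes, so it served only for gene names, transcript lengths, overlaps and transcript sequences, and no coordinates are given. It held the names of 50711 of the 56674 rows.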

Results

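Liver RNA was profiled in male C57BL/6 mice, a common inbred laboratory strain, kept for 71 weeks on normal chow (control, 3 libraries) or on chow containing polypropylene black microplastic (PB-MP, 3 libraries). The comparison of PB-MP with control addressed whether prolonged dietary exposure to this plastic alters hepatic gene expression, with metabolism named in the title of the series. Each value is the raw read count of a gene in a poly(A)-selected library. The control libraries held 75897165, 68357478 and 112566641 counted reads in replicates 1, 2 and 3, and the PB-MP libraries held 70603124, 81174742 and 90483598. A count of 3 reads, taken here as the limit that a count of 0 allows, corresponds to 0.0285 to 0.0495 CPM (counts scaled to TMM-adjusted library size, written ppm for unscaled shares of reads), and such limits cover counting error only. The labels do not say that the 3 libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

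The libraries differed in composition along with the diet. The 13 mRNAs encoded by the mitochondrial genome took 14.6% ± 0.446 of the counted reads in control and 9.43% ± 0.704 in PB-MP (SD, n = 3 each), and the 2 groups did not overlap (exact permutation test, two-sided, p = 0.1, the smallest p that 3 against 3 libraries allow). The transcript of Alb, which encodes albumin, took 4.79% ± 0.610 in control and 5.66% ± 0.0805 in PB-MP (exact permutation p = 0.1). These shares are unscaled, and the TMM scaling factors separated the groups too, at 0.887 to 0.961 in control and 1.04 to 1.12 in PB-MP. The scaled estimate for Alb, given with the metabolic genes below, was near 0. Between 23095 and 23872 rows had at least 1 read in the control libraries, against 24865 to 25133 in the PB-MP libraries (exact permutation p = 0.1). The 18S ribosomal RNA row Rn18s-rs5 did not follow the diet. It took 11.2% of the reads of control replicate 2 and 9.42% of PB-MP replicate 2, and between 0.707% and 3.61% in the other 4 libraries. Reads of 5S ribosomal RNA came to 3.11 ppm of the reads in PB-MP replicate 3 and to between 174 and 1008 ppm in the other 5 libraries.

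**Figure D1:**
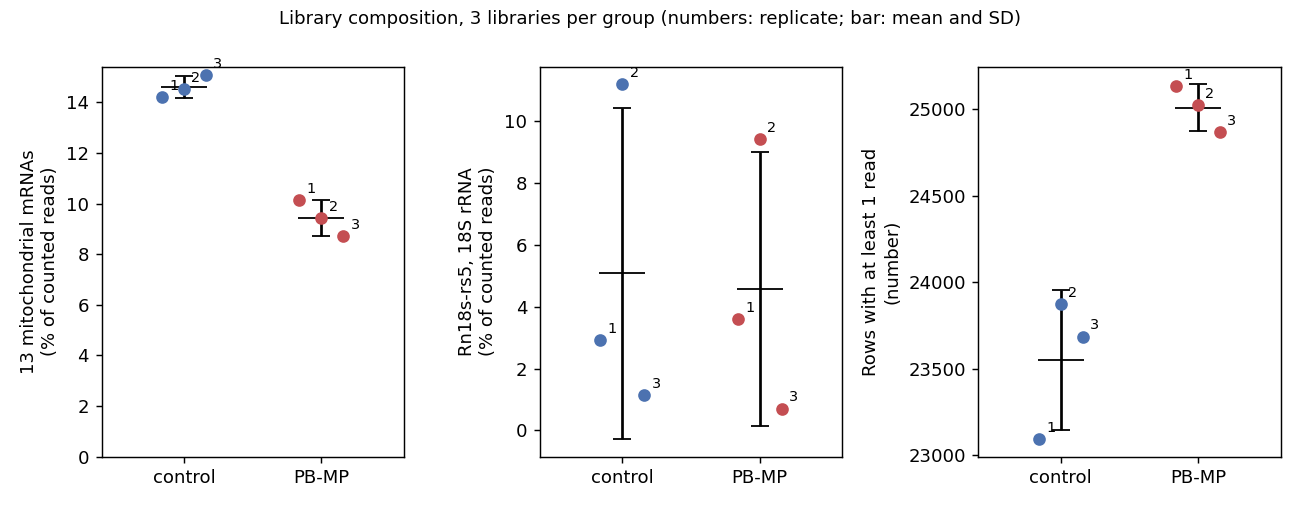
Library composition in 6 liver libraries. The panels plot the share of counted reads from 13 mitochondrial mRNAs (%), the share from the 18S rRNA row Rn18s-rs5 (%), and the number of rows with at least 1 read (axis not starting at 0), with 1 point per library and the mean and SD of 3 libraries per group. The mitochondrial share was 14.2% to 15.1% in control and 8.73% to 10.1% in PB-MP.

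Over all 17871 genes tested, the libraries lay closer on average to their own group than to the other, though not in every pair. The mean distance between groups exceeded the mean distance within groups by 15.3 log2 CPM units, against at most 11.8 for any other split of the 6 libraries (exact permutation test over 10 splits, one-sided, p = 0.1, the smallest possible). The first principal component held 33.9% of the variance and placed the control libraries at -70.1, -2.38 and -66.0 and the PB-MP libraries at 46.5, 32.2 and 59.8. The second held 25.0% and set PB-MP replicate 3, at 77.2, apart from PB-MP replicates 1 and 2, at -22.5 and -34.0. Control replicate 2 correlated with PB-MP replicates 1, 2 and 3 at 0.953, 0.959 and 0.931 (Pearson, log2 CPM), and with control replicates 1 and 3 at 0.946 and 0.953. With a stricter filter on low counts, and on the 500 genes of highest variance, the exact p of the separation was 0.2.

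**Figure D2:**
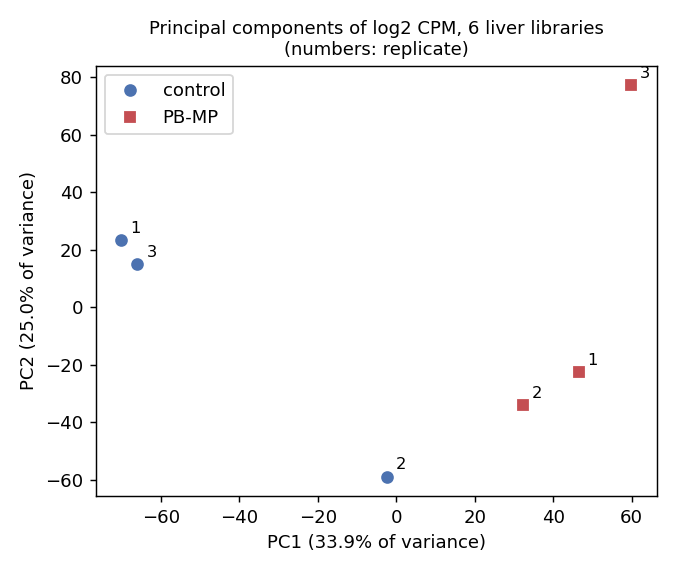
First and second principal components of log2 CPM (unitless coordinates, with the share of variance on each axis) for 3 control and 3 PB-MP libraries, 1 point per library. Control replicate 2, at -2.38 on the first component, lies nearest to the PB-MP libraries, at 32.2 to 59.8.

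No single gene differed between PB-MP and control past the threshold. Of 17871 genes tested, 0 were higher and 0 were lower at an adjusted p below 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment, smallest adjusted p = 0.124). At an unadjusted p below 0.05 there were 2161 genes, 1314 of them higher and 847 lower in PB-MP, where chance alone gives 894. With 1 library left out in turn that number ran from 1472 without control replicate 3 to 3338 without control replicate 2. With limma-voom and library quality weights it was 4185. The groups did not overlap for 3547 genes (19.8%), where chance gives 10% for 3 against 3 libraries. Of the other tools run, limma-voom called 0 genes and DESeq2 called 513, of which 361 were higher and 152 lower. All 483 of the DESeq2 genes that edgeR tested had an unadjusted edgeR p below 0.05. Without control replicate 1, edgeR called 1 gene, Cyp4a32, at an adjusted p of 0.00588, named after its values were seen. It stood at 67.4 CPM in control replicate 1, at 2.06 and 1.65 in control replicates 2 and 3, and at 81.3 or more in each PB-MP library. Without control replicate 2 and PB-MP replicate 3, left out together after the data were seen, edgeR called 2 genes, Dennd5b and Igkc, and the number at an unadjusted p below 0.05 was 4316.

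The genes with the smallest p among those whose groups did not overlap are given here as values, since none passed at an adjusted p below 0.05. Log2 fold changes are PB-MP over control with their SE, and CPM are means ± SD (n = 3). Mprip, which encodes a protein that ties myosin phosphatase to the actin cytoskeleton, had 30.1 ± 0.310 CPM in control and 68.8 ± 3.28 in PB-MP (log2 fold change 1.19 ± 0.13, edgeR adjusted p = 0.207). Vegfa, an angiogenic growth factor, had 42.9 ± 11.1 and 110.5 ± 15.5 CPM (1.36 ± 0.22), and Cxcl1, a chemokine that attracts neutrophils, had 1.54 ± 0.220 and 5.51 ± 1.55 CPM (1.83 ± 0.29). Gckr, the regulator of glucokinase, had 42.7 ± 13.1 and 125 ± 15.7 CPM (1.55 ± 0.26), and Snrnp70, a spliceosome component, had 33.4 ± 9.86 and 94.1 ± 9.72 CPM. The log2 fold changes of Fgl1, a hepatocyte-secreted protein, of Adamts6, an extracellular protease, and of H2-Q5, a class I histocompatibility gene with close paralogs among which reads may be split, were 1.21 ± 0.21, 1.79 ± 0.28 and 1.72 ± 0.29. In the other direction, Spsb4 had 2.68 ± 0.385 CPM in control and 0.297 ± 0.0395 in PB-MP (log2 fold change -3.17 ± 0.27, edgeR adjusted p = 0.124). Actb, which encodes cytoplasmic beta-actin, had 401 ± 21.9 and 204 ± 9.07 CPM (-0.98 ± 0.14), and Cyp4a12a, a male-biased fatty acid hydroxylase, had 426 ± 79.7 and 133 ± 41.1 CPM (-1.68 ± 0.27). The log2 fold changes of Slc22a30, an organic anion transporter family member, Ecpas, a proteasome adaptor, and Ncoa6, a nuclear receptor coactivator, were -1.26 ± 0.19, -1.86 ± 0.30 and -2.22 ± 0.37. Those of the mitochondrial transfer RNA mt-Tt and of the small noncoding RNA Bc1 were -1.85 ± 0.30 and -2.14 ± 0.36. In DESeq2 all 16 of these genes passed at an adjusted p below 0.05, which is no independent evidence, as their edgeR p on the same counts chose them.

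For the metabolic genes, the size of any change was bounded as well as tested. Of 278 tested members of the 11 metabolism lists, 0 passed in edgeR at an adjusted p below 0.05, whether adjusted over all genes or over the union of these lists alone (smallest adjusted p over the union = 0.120), and 33 had an unadjusted p below 0.05. DESeq2 called 10 of the metabolic genes, Gckr and Mlxipl higher and Pfkfb1, Cidec, Abcc4, mt-Nd1, mt-Nd4l, mt-Co1, mt-Co2 and mt-Atp6 lower, and limma-voom called 0. The 95% interval of the log2 fold change lay within -1 to 1 for 172 of the 278 (61.9%), against 8170 of all 17871 genes (45.7%). The median half-width of the interval was 0.58 for metabolic genes. For the other 106 genes a 2-fold difference was not excluded. Fasn, the fatty acid synthase, had a log2 fold change of -0.29 ± 0.35 (SE), Cpt1a, which controls fatty acid entry into mitochondria, 0.04 ± 0.24, Pck1, an enzyme of gluconeogenesis, -0.12 ± 0.37, and Alb 0.03 ± 0.24. The sign of these estimates for Alb, Cpt1a, Fasn and Pck1 turned under some settings, within their SE. Scd1, a fatty acid desaturase, was at -0.82 ± 0.52 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 0.47 ± 0.43 with 0.795 ± 0.392 CPM in control. In a simulation of this comparison, the edgeR test recovered 47.0% of genes changed 4-fold, 2.99% of those changed 2-fold and 0.00% of those changed 1.5-fold. The changed genes there were drawn from those with a mean of at least 1 CPM, so the shares do not cover genes of lower level.

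As groups, 16 of 44 testable gene lists differed from the other genes, 3 higher and 13 lower in PB-MP (limma camera on voom values, preset correlation of 0.01, adjusted p below 0.05 over the 44 lists). With an estimated correlation 0 lists passed, and with fry, which asks whether a list moves on balance one way, 0 passed. Fry found 5 lists changed in either direction, which asks whether members move, up or down. They were the cell cycle, mitochondrially encoded, inflammatory cytokine, NRF2 and heat shock lists (fry adjusted p of 4.10e-04, 0.00110, 0.00560, 0.00858 and 0.0114). Splits of the same libraries that mix the groups gave 5 to 17 lists past the threshold with the preset correlation. Between the real groups, the number of members that passed over all genes in edgeR was 0 in every list, so examples are given as values. DESeq2 called 30 members of 24 lists. List medians are of the voom log2 fold changes that the list test uses. Library size alone as the scaling raised the median of all genes to 0.23 from 0.01, which brings most of the negative medians below nearer to 0, and the medians that follow are relative to the scaling factors of the trimmed mean of M-values (TMM).

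Mitochondrially encoded mRNAs were the metabolism list furthest from the other genes, at a median log2 fold change of -0.85 (adjusted p = 1.72e-09; adjusted p = 0.242 with an estimated correlation). All 13 estimates were below 0, the libraries of the groups did not overlap for 10 of the 13, and 8 passed adjusted over the list alone. mt-Nd1, a subunit of respiratory complex I, had 12898 ± 1988 CPM in control and 6059 ± 545 in PB-MP (log2 fold change -1.09 ± 0.23 (SE), edgeR adjusted p = 0.207), and mt-Co2, a subunit of complex IV, had 8855 ± 486 and 4921 ± 468 (-0.85 ± 0.20, adjusted p = 0.234). The median was -0.53 without control replicate 2 and PB-MP replicate 3 together (adjusted p = 6.90e-07). These mRNAs have copies in nuclear DNA with which reads can be shared. The 38 nuclear-encoded oxidative phosphorylation genes had a median of -0.20 (adjusted p = 0.00121; adjusted p = 0.704 with an estimated correlation). The median of the nuclear-encoded genes depended on the libraries used. It was -0.11 without PB-MP replicate 2, where the call was lost (adjusted p = 0.0933), and -0.11 without PB-MP replicate 1 (adjusted p = 0.0414). It was -0.32 without control replicate 2 (adjusted p = 7.63e-05), -0.35 without PB-MP replicate 3 (adjusted p = 4.08e-12) and -0.44 without both of the last 2 (adjusted p = 3.39e-13). With quality weights it was -0.34 (adjusted p = 4.18e-08), and with library size only it was 0.02, below the 0.23 of all genes. Among them Cox6b1 and Cox5a, subunits of complex IV, had log2 fold changes of -0.53 ± 0.21 and -0.59 ± 0.25.

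Fatty acid and triglyceride synthesis genes had a median of -0.32 over 23 members, 22 of them with estimates below 0 (adjusted p = 0.00636; adjusted p = 0.704 with an estimated correlation). The exception was Mlxipl, which encodes the carbohydrate-responsive transcription factor ChREBP, with 56.1 ± 5.15 CPM in control and 151 ± 54.1 in PB-MP (log2 fold change 1.43 ± 0.28), and it was the 1 member that passed adjusted over the list alone. Me1, malic enzyme, was at -0.85 ± 0.33. Without control replicate 1, PB-MP replicate 2 or PB-MP replicate 3 this list no longer passed (adjusted p of 0.0533, 0.0515 and 0.0585), at medians of -0.27, -0.32 and -0.29 that stayed near the value with all libraries. The median was -0.52 without PB-MP replicate 1 (adjusted p = 7.82e-04) and -0.49 without control replicate 2 and PB-MP replicate 3 together (adjusted p = 0.00458). Fatty acid oxidation and PPAR-alpha target genes had a median of -0.22 over 32 members (adjusted p = 0.00901; adjusted p = 0.704 with an estimated correlation), with Vnn1 at -0.55 ± 0.21 and Acaa1b, a peroxisomal thiolase, at -0.77 ± 0.31. This call was lost without control replicate 1, control replicate 3 or PB-MP replicate 2, at medians of -0.17, -0.18 and -0.13 (adjusted p of 0.0611, 0.102 and 0.147), and with library size only (-0.00, adjusted p = 0.0708). The median was -0.38 without control replicate 2 and PB-MP replicate 3 together (adjusted p = 8.19e-05). Adipocyte markers were lower along with these lipid lists (median -2.72 over 4 testable members, 3 of them below 0, adjusted p = 0.0320; adjusted p = 0.520 with an estimated correlation).

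The other 7 metabolism lists did not pass with all libraries. Lipid droplet and steatosis genes had a median of -0.18 (adjusted p = 0.0588), with Cidec, a lipid droplet protein, at 37.8 ± 22.3 CPM in control and 10.2 ± 5.16 in PB-MP and Fitm2 at a log2 fold change of -0.88 ± 0.26. Cidec stood at 57.9, 13.9 and 41.7 CPM in control replicates 1, 2 and 3. The adipocyte marker Cfd was likewise lowest among controls in replicate 2, at 2.19 CPM against 8.71 or more. The lipid droplet list passed without control replicate 2 (-0.41, adjusted p = 0.00199), PB-MP replicate 1 (-0.21, adjusted p = 0.0420) or PB-MP replicate 3 (-0.33, adjusted p = 0.0300), and without control replicate 2 and PB-MP replicate 3 together (-0.52, adjusted p = 0.00297). It also passed with quality weights (-0.34, adjusted p = 0.0172) and with no filter (-0.18, adjusted p = 0.0320). In the other direction, its median was -0.11 without control replicate 3 (adjusted p = 0.265). Gluconeogenesis, glycolysis and glycogen genes had a median of -0.15 (adjusted p = 0.0769), and 2 members passed adjusted over the list alone, Gckr and, in the other direction, Pfkfb1 at -1.36 ± 0.26. Without control replicate 2 this list passed (-0.28, adjusted p = 0.0108), as it did without control replicate 2 and PB-MP replicate 3 together (-0.25, adjusted p = 0.0109), while without control replicate 1 the median was -0.04 (adjusted p = 0.362). Medians were 0.16 for cholesterol synthesis and SREBP2 targets (adjusted p = 0.820; 0.28 without PB-MP replicate 2, adjusted p = 0.0397, and -0.02 without control replicate 2), -0.08 for bile acid synthesis and transport (adjusted p = 0.332; Abcc4 at -1.44 ± 0.44, Abcg8 at -0.39 ± 0.15) and 0.03 for insulin and FOXO1 signalling (adjusted p = 0.855; Foxo1 at -0.64 ± 0.25, Enho at 0.80 ± 0.35). They were -0.09 for lipoproteins and apolipoproteins (adjusted p = 0.306; Pltp at -3.51 ± 1.08, Apoc4 at -0.60 ± 0.21) and 0.05 for amino acid breakdown and urea cycle genes (adjusted p = 0.834; Gpt at -1.36 ± 0.44, Bckdha at -0.32 ± 0.19). Pltp varied between libraries, at 188, 36.3 and 171 CPM in control replicates 1, 2 and 3 and at 2.70, 28.6 and 3.41 CPM in PB-MP replicates 1, 2 and 3. The mean of the amino acid list was -0.03, and its test pointed down, against its median.

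Among stress lists, genes of fibrosis and stellate cell activation had a median of -0.50 over 25 members, 23 of them below 0 (adjusted p = 4.34e-06; adjusted p = 0.520 with an estimated correlation). Col1a1, a chain of type I collagen, had 4.64 ± 0.797 CPM in control and 2.25 ± 0.573 in PB-MP (log2 fold change -1.04 ± 0.28, edgeR adjusted p = 0.255), and Col1a2 was at -1.04 ± 0.30. Markers of stellate cells and fibroblasts were lower too (median -0.41, adjusted p = 0.00591; adjusted p = 0.704 with an estimated correlation), but not in every PB-MP library. Their mean deviation was -0.91 and -0.23 in PB-MP replicates 1 and 3 and 0.37 in PB-MP replicate 2, above all 3 controls (0.15 to 0.35). NRF2 and antioxidant genes had a median of -0.27 over 33 members (adjusted p = 4.80e-04; adjusted p = 0.520 with an estimated correlation). Gstm1, a glutathione transferase with close paralogs, had 2371 ± 511 CPM in control and 1050.2 ± 44.8 in PB-MP (-1.17 ± 0.22) and passed adjusted over the list alone, while Hmox1, heme oxygenase, was at 0.57 ± 0.24. The NRF2 median was -0.45 without control replicate 2 and PB-MP replicate 3 together (adjusted p = 5.34e-05). Cell cycle genes had a median of -0.50 over 26 members (adjusted p = 7.63e-04; adjusted p = 0.507 with an estimated correlation), with Mcm6 at -0.65 ± 0.26, E2f1 at -0.54 ± 0.25 and Cdc20, named because it alone passed adjusted over the list alone, at -1.76 ± 0.32. With the stricter filter the cell cycle call was lost (-0.31, adjusted p = 0.185). The libraries of the groups did not overlap in the mean of the fibrosis, the NRF2 or the cell cycle list.

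Xenobiotic metabolism genes had a median of -0.24 over 35 members (adjusted p = 0.00591; adjusted p = 0.652 with an estimated correlation), and this call was lost without control replicate 3 (-0.16, adjusted p = 0.157). Ephx1, an epoxide hydrolase, was at -0.69 ± 0.19, Gstm3 at -1.27 ± 0.33, Cyp1a1, the classical target of the aryl hydrocarbon receptor, at -0.84 ± 0.26 with 1.05 ± 0.127 CPM in control, Cyp2b10 at -1.24 ± 0.48 and Cyp3a11, whose sign turned under some settings, at -0.04 ± 0.25. The unfolded protein and integrated stress response list had a median of -0.24 (adjusted p = 0.0149; adjusted p = 0.704 with an estimated correlation), with the chaperones Calr at -0.45 ± 0.15 and Pdia4 at -0.35 ± 0.17, and was not past the threshold without control replicate 2 or PB-MP replicate 1 (-0.19 and -0.20, adjusted p of 0.126 and 0.131) or with library size only (-0.02, adjusted p = 0.0674). The interferon response list had a median of -0.12 (adjusted p = 0.0449; adjusted p = 0.704 with an estimated correlation), with Rtp4 at -1.45 ± 0.38 and Bst2 at -0.60 ± 0.20. This call was lost without control replicate 2, PB-MP replicate 2 or PB-MP replicate 3, at medians of -0.09, -0.04 and -0.10 (adjusted p of 0.264, 0.587 and 0.0737). It was also lost without control replicate 2 and PB-MP replicate 3 together (-0.03, adjusted p = 0.384) and with quality weights (-0.01, adjusted p = 0.424). Without control replicate 1, control replicate 3 or PB-MP replicate 1 the interferon median was -0.32, -0.19 and -0.34 (adjusted p of 0.00745, 0.0419 and 1.23e-04). With library size only its sign turned (0.09, adjusted p = 0.0185, below the 0.23 of all genes).

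The remaining stress lists did not pass in camera with all libraries, though fry found the inflammatory cytokine and heat shock lists changed in either direction. Inflammatory cytokines and NF-kappaB targets had a median of 0.31 (adjusted p = 0.243), with Cxcl1 passing adjusted over the list alone and Nfkbiz at 1.06 ± 0.27. The acute phase list had a median of -0.01 against a mean of 0.09 and an upward test (adjusted p = 0.855), with Itih3 at 0.66 ± 0.17, Mt2 at 1.82 ± 0.79 and Saa1 at 0.55 ± 0.26. Medians were -0.11 for heat shock and chaperones (adjusted p = 0.0929; Hspb1 at -1.43 ± 0.36, Hspe1 at -0.46 ± 0.15), 0.08 for immediate early genes (adjusted p = 0.872; Jund at -0.59 ± 0.14, Zfp36 at 0.57 ± 0.16) and -0.13 for p53 targets and senescence (adjusted p = 0.243; Phlda3 at -0.89 ± 0.32, Cdkn1a at -1.96 ± 0.74). Cdkn1a stood at 49.9 CPM in control replicate 1 and at 4.57 to 10.9 in every other library. The heat shock list passed without control replicate 1, control replicate 3 or PB-MP replicate 3 (-0.18, -0.11 and -0.16, adjusted p of 0.0418, 0.0444 and 0.0455), and it was further from the threshold without control replicate 2 (adjusted p = 0.347) or PB-MP replicate 2 (-0.07). Medians were -0.14 for lysosome and phagocytosis (adjusted p = 0.243; Mcoln1 at 0.51 ± 0.16, Hexa at -0.62 ± 0.20), 0.20 for the circadian clock (adjusted p = 0.575; Per2 at 0.94 ± 0.33, Cry1 at -0.82 ± 0.38) and -0.21 for fetal liver and tumour markers (adjusted p = 0.626; Afp at 1.52 ± 0.44, Ly6d at -0.74 ± 0.38). With 1 library left out in turn, the circadian median ran from -0.01 to 0.40 and the fetal and tumour median from -0.24 to 0.06.

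Among hepatocyte lists, male-biased liver genes had a median of -0.31 over 23 members, 15 of them below 0 (adjusted p = 0.00129; adjusted p = 0.652 with an estimated correlation). The mean deviation of this list was 0.17 in PB-MP replicate 3, above control replicates 1 and 3 (0.03 and -0.00). Cyp4a12a and Cyp4a12b, near-identical paralogs among which reads may be split, were at -1.68 ± 0.27 and -1.87 ± 0.32, and with Elovl3 (-1.23 ± 0.34) and Selenbp2 (-0.66 ± 0.16) were the 4 members that passed adjusted over the list alone. The median was -0.18 without control replicate 2 (adjusted p = 0.0462). The list named nuclear-retained long noncoding RNAs had a median of 0.70 over 7 members, all 7 with estimates above 0 (adjusted p = 8.90e-04; adjusted p = 0.589 with an estimated correlation). The name is a label only, since the list also holds Gas5 and Snhg1, host genes of small nucleolar RNAs, and where the RNAs lie in the cell was not measured. Snhg11, with means of 12.8 CPM in control and 36.8 in PB-MP, was at 1.52 ± 0.40, Snhg1 was at 0.69 ± 0.18, and these and Meg3 (1.69 ± 0.50) passed adjusted over the list alone. Without control replicate 2 the median of these RNAs was 1.13 (adjusted p = 7.13e-05), and without control replicate 2 and PB-MP replicate 3 together it was 1.25 (adjusted p = 6.68e-05). The share of mitochondrial mRNA and the number of rows with a read moved with the groups as well. With all libraries, female-biased genes did not pass (median 0.11, adjusted p = 0.885; Cux2 at 2.97 ± 0.66, Cyp2a4 at -0.82 ± 0.35), nor did pericentral genes (-0.21, adjusted p = 0.0769; Aldh3a2 at -0.57 ± 0.25), periportal genes (0.15, adjusted p = 0.368; Ctsc at 0.57 ± 0.15, Hsd17b13 at 0.47 ± 0.21) or ribosomal proteins (0.02, adjusted p = 0.770, with a test that pointed down; Rpl18 at -0.34 ± 0.15, Rps29 at -0.43 ± 0.19). The ribosomal protein list changed sign and passed without PB-MP replicate 3 (-0.27, adjusted p = 7.11e-09), without control replicate 2 and PB-MP replicate 3 together (-0.25, adjusted p = 5.41e-06) and with quality weights (-0.20, adjusted p = 0.00264). The pericentral list passed without control replicate 2 (-0.35, adjusted p = 0.00658), without PB-MP replicate 1 (-0.25, adjusted p = 0.0137) and with no filter (-0.20, adjusted p = 0.0402). Its median was -0.10 without PB-MP replicate 3 (adjusted p = 0.334) and -0.10 without control replicate 3 (adjusted p = 0.413).

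Among cell type marker lists, neutrophil and mast cell markers had a median of 1.28 over 6 testable members (adjusted p = 0.00591; adjusted p = 0.520 with an estimated correlation), at low levels. Csf3r, the granulocyte colony-stimulating factor receptor, had 0.658 ± 0.184 CPM in control and 1.65 ± 0.440 in PB-MP, and S100a9 had means of 0.338 and 1.27 CPM. Both passed adjusted over the list alone. With no filter the neutrophil and mast cell call was lost (0.40, adjusted p = 0.168). Kupffer cell markers, of the resident liver macrophages, had a median of 0.44 over 14 members, 13 of them above 0 (adjusted p = 0.00636; adjusted p = 0.704 with an estimated correlation). Marco, a macrophage scavenger receptor, had 30.3 CPM in PB-MP replicate 3 and 1.55 to 4.61 in the other 5 libraries. Without PB-MP replicate 3 the median of the Kupffer list was 0.12 (adjusted p = 0.236), and without control replicate 2 it was 0.32 (adjusted p = 0.168). Without both of these libraries the sign of the Kupffer median turned (-0.01, adjusted p = 0.858). It was 0.18 with quality weights (adjusted p = 0.218), and without PB-MP replicate 2 it was 0.67 (adjusted p = 9.83e-04). Stellate cell and fibroblast markers had a median of -0.41 (adjusted p = 0.00591; adjusted p = 0.704 with an estimated correlation; Cygb at -0.59 ± 0.24), and without PB-MP replicate 1 the median was -0.19 (adjusted p = 0.115). It was -0.82 without PB-MP replicate 2 (adjusted p = 7.14e-06) and -0.49 without control replicate 2 and PB-MP replicate 3 together (adjusted p = 0.0788). Adipocyte markers had a median of -2.72 over 4 testable members (adjusted p = 0.0320; adjusted p = 0.520 with an estimated correlation), with Cfd, the adipokine adipsin, at 7.63 ± 4.98 CPM in control and 0.880 ± 0.370 in PB-MP. Cfd, Cidea and Retn passed adjusted over the list alone. Retn had means of 0.254 CPM in control and 0.0294 in PB-MP, the latter near the level of 3 reads, and Cidea is also a member of the lipid droplet list. The adipocyte list call was lost without PB-MP replicate 2 or PB-MP replicate 3 (-2.19 and -3.14, adjusted p of 0.1495 and 0.0527), with no filter (-1.01, adjusted p = 0.0954) and with the stricter filter (-2.49, adjusted p = 0.182).

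The other marker lists did not pass with all libraries. Hepatocyte markers had a median of -0.00 with an upward test (adjusted p = 0.855; Apoa1 at 1.18 ± 0.56). Medians were -0.31 for monocyte-derived macrophages and dendritic cells (adjusted p = 0.207; H2-Aa at -0.60 ± 0.19; -0.38 without PB-MP replicate 3, adjusted p = 0.0362, and adjusted p = 0.742 without control replicate 2), 0.04 for sinusoidal endothelium (adjusted p = 0.834; Egfl7 at 0.66 ± 0.33) and 0.17 for cholangiocytes, with a downward test (adjusted p = 0.793; Krt23, which passed adjusted over the list alone, at -1.70 ± 0.32). They were -0.26 for T and NK cells (adjusted p = 0.119; Trac at -0.84 ± 0.27), -0.46 for B and plasma cells (adjusted p = 0.0606; Jchain at -2.30 ± 0.67), 0.03 for erythroid cells (adjusted p = 0.733; Hbb-bs at 0.87 ± 0.36), -0.61 for skeletal and smooth muscle (adjusted p = 0.146; Des at -0.66 ± 0.27) and -0.21 for mesothelium (adjusted p = 0.834; Upk3b at -1.27 ± 0.77). With 1 library left out in turn, the mesothelial median ran from -0.66 to 0.55 and the cholangiocyte median from -0.07 to 0.58, so the signs of both depended on the libraries used. The T and NK cell list passed without control replicate 3 (-0.51, adjusted p = 0.0222) and with library size only (-0.04, adjusted p = 0.0378), and without control replicate 2 its adjusted p was 0.641. The B and plasma cell list passed without control replicate 3 (-1.05, adjusted p = 1.31e-05), and without PB-MP replicate 3 (-0.72, adjusted p = 0.0300). It also passed with library size only (-0.26, adjusted p = 0.00535), with no filter (-0.47, adjusted p = 0.0308) and with ribosomal RNA and mitochondrial rows left out (-0.44, adjusted p = 0.0429). Its mean deviation was 1.29 in control replicate 2 against -0.03 and -0.84 in control replicates 1 and 3, and without control replicate 2 its median was -0.18 (adjusted p = 0.641). Exocrine pancreas markers and gallbladder and intestinal epithelium markers had 2 testable members each, too few for the list test. Cela1 was at 0.59 ± 0.37 and Lgals4 at 1.76 ± 0.45. Lgals4 passed adjusted over its list alone, that is over 2 genes, without regard to the number of lists.

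**Figure D3:**
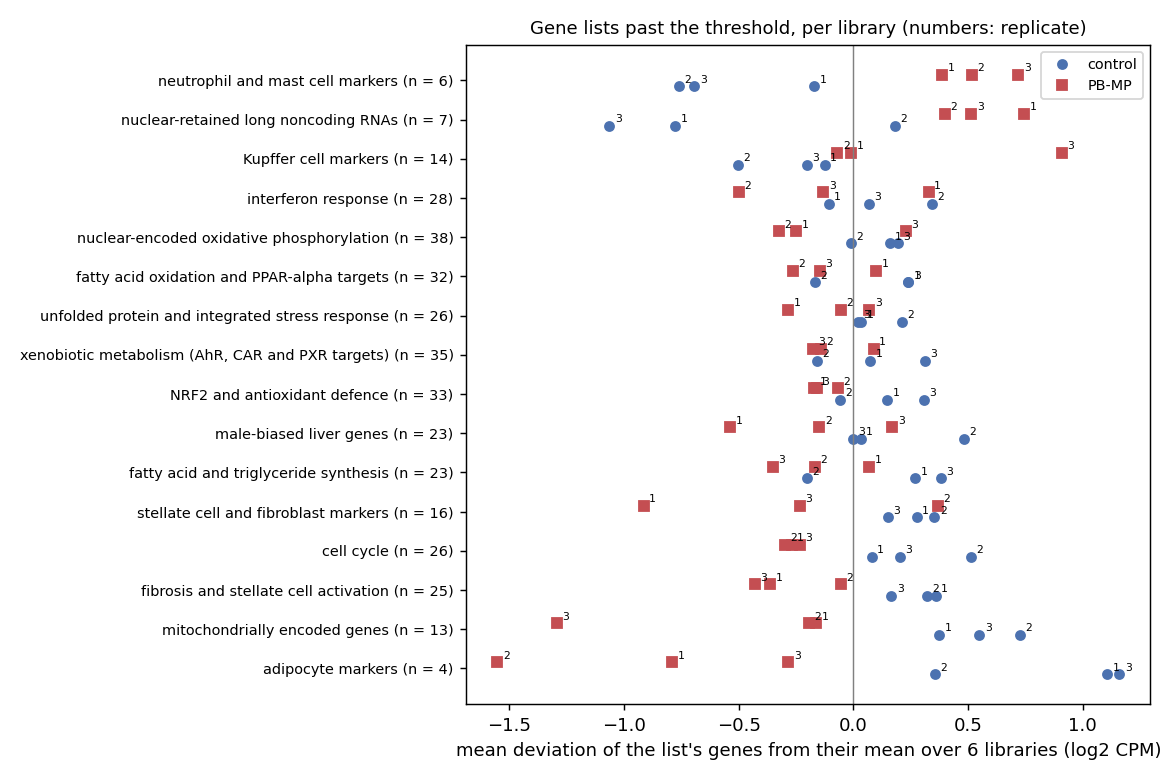
The 16 gene lists past the threshold with a preset correlation, per library. Each point is the mean deviation, in log2 CPM, of a list's tested genes in 1 library from their means over all 6 libraries (circles, control; squares, PB-MP; n, genes). The groups did not overlap for 8 of the 16 lists, and PB-MP replicate 3 stood at 0.91 in the Kupffer list and at -1.29 in the mitochondrial list, where 22 reads of mt-Nd4 were counted in that library against 28480 to 67595 in the other 5.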

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

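The alternatives that left out ribosomal RNA and mitochondrial rows, genes nearly lost in 1 library, or control replicate 2 with PB-MP replicate 3 were chosen after seeing the data. The count of 0 genes changed was also given by relative log expression factors, library size only, no filter, the stricter filter, limma-voom with or without quality weights, robust estimation, an adjusted p below 0.1 and the first 2 of those late alternatives. It became 513 genes with DESeq2 (361 higher, 152 lower), 1203 at an unadjusted p below 0.05 with a 2-fold difference (861 higher, 342 lower), and 2 genes, both higher, without control replicate 2 and PB-MP replicate 3. With 1 library left out in turn it ran from 0 to 1 gene changed, and from 0 to 1 gene higher. The cause of the DESeq2 count was not tested. With library size only, 89.0% of the genes at an unadjusted p below 0.05 were higher in PB-MP, against 60.8% with TMM. The 16 gene lists became 0 (0 higher, 0 lower) with an estimated correlation and 0 (0 higher, 0 lower) with fry. With 1 library left out there were 12 to 17 lists past the threshold, of which 8 to 15 were lower, the fewest without PB-MP replicate 2. Of the 16 lists, 7 stayed past with each library left out in turn. Metabolic genes bounded within a log2 fold change of 1 numbered 165 with limma-voom, 176 with DESeq2 and 135 to 156 with 1 library left out. The separation of the groups had an exact p of 0.1 to 0.2 under its 4 alternatives. Over the 99 named genes, 1725 values kept their direction and side of the threshold, 36 kept their direction and passed, all with DESeq2, and 15 of genes not past the threshold changed sign. The table of all samples gave no separate value because it equals the single files. Depth limits genes near 0.0285 to 0.0495 CPM, the level of 3 reads.

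The replicate numbers were not taken as pairs, since deviations from the group means correlated at -0.09, 0.09 and 0.08 across the 3 numbers, and the labels give no shared source. Of the control libraries 2 of 3, and of the PB-MP libraries 2 of 3, correlated best with their own number, and the 18S share had the same order in both groups (2.92%, 11.2% and 1.15% in control, 3.61%, 9.42% and 0.707% in PB-MP), so a shared step per number is not excluded. A fit with a replicate block called 0 genes (1836 at an unadjusted p below 0.05), 17 lists (3 higher, 14 lower) and 166 bounded metabolic genes. With the block the lipid droplet list (adjusted p = 0.00604) and the B and plasma cell list (adjusted p = 0.0146) were past the threshold and the interferon list was not (adjusted p = 0.0590).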

Other observations

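The tests of mitochondrial tRNAs, immunoglobulin genes, nuclear copies, mitochondrial ribosomal RNA and overlapping genes, the counts over splits, the fit without 2 libraries together and the use of single left-out libraries to weigh a pattern were chosen after the results were seen, while the fits without each library had been planned. The transfer RNAs of the mitochondrial genome, which belong to no list of the report, had lower values in PB-MP too. Of 22 mitochondrial tRNA genes 17 could be tested, and all 17 had log2 fold changes below 0 (median -1.37), 15 without overlap between the groups and 0 past the threshold (smallest edgeR adjusted p = 0.207). Together they took 2083 ± 641 ppm of the reads in control and 986 ± 172 ppm in PB-MP (SD, n = 3 each).

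Of 96 immunoglobulin genes tested, a set chosen by name after the data were seen, 87 had log2 fold changes below 0. Of these genes edgeR called 0, and DESeq2, which tested others as well, called 17 lower and 1 higher. The count of 87 may rest on control replicate 2. The B and plasma cell list, which holds some of these genes, had a mean deviation of 1.29 there and of -0.03 and -0.84 in control replicates 1 and 3. Without control replicate 2 the median of that list was -0.18 (camera adjusted p = 0.641). Igkc, the kappa light chain of plasma cells, stood at 0.137, 124.5 and 0.114 CPM in control replicates 1, 2 and 3 and at 19.1, 21.3 and 60.4 CPM in PB-MP, named after its values were seen. Dennd5b stood at 93.6 and 86.9 CPM in PB-MP replicates 1 and 2, and at 0.906 to 2.06 CPM in the other 4 libraries.

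The first pattern is the lower level of mitochondrially encoded mRNAs in PB-MP. A shift of reads to nuclear copies stays open. The 14 tested nuclear genes that share 31-base stretches with these mRNAs had a median log2 fold change of -1.16, lower rather than higher. Among them Gm28661 stood at 8815 CPM in control and 4881 in PB-MP, close to mt-Co2 at 8855 and 4921. Reads may thus have been counted for both genes, and such copies would fall with the mRNAs whatever the cause. A single library is argued against, since with each library left out in turn the list's median stayed at -0.66 or below. The adjusted p of camera in these fits ran from 1.68e-10 to 2.65e-06 with the preset correlation, which may understate how these mRNAs vary together. With all libraries and an estimated correlation it was 0.242. A lower yield of every mitochondrial RNA stays open, because the mitochondrial tRNAs were lower as well, and the intervals of the ribosomal RNAs mt-Rnr1 and mt-Rnr2 reach down to -1.93 and hold both 0 and the median of the mRNAs. The diet, and any handling of the tissue that differed between the groups, stay open as untested.

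The second pattern is that 73 genes were nearly lost in 1 library only, at least 2.5 log2 units below the mean of the other 5 libraries, whose range was under 1.5 units and whose mean was at least 4 CPM, 39 times in control and 34 times in PB-MP libraries. In control replicate 1, Tasor had 2 reads where the other libraries predict 1466, and Sec14l2 had 23.3 CPM against 320 to 505 in the others. In PB-MP replicate 3, Rnf152 had 0 reads, which allows up to 0.0308 CPM, against 17.2 to 28.7 CPM elsewhere. Reads counted for an overlapping gene stay open. In the 26 losses with such a gene among those tested, these genes gained at least 50% of the missing reads in 7.69%. However, an overlapping gene raised in 1 library only could fail the filter and was then not counted. The overlaps also came from GENCODE M21, not from the annotation used for counting, which is not given. Transcript length stays open, with 68.6% of the lost genes over the median length (exact 95% interval 56.4% to 79.1%), and no biological explanation was tested, since the losses lie in single libraries.

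The third pattern is the higher level of Kupffer cell markers in PB-MP. It may rest on 1 library, since without PB-MP replicate 3 the median log2 fold change was 0.12 (adjusted p = 0.236, and from 7.82e-04 to 0.236 over the 6 libraries left out in turn), and without control replicate 2 it also missed the threshold (adjusted p = 0.168). Without both of these libraries the median was -0.01 (adjusted p = 0.858). A lower share of hepatocytes in PB-MP replicate 3 is argued against as the whole cause, since the stellate and the T and NK cell lists lay below their means there (-0.23 and -0.25). The sinusoidal endothelial and the B and plasma cell lists lay above theirs (0.23 and 0.06). The Kupffer list (0.91 above its mean over the libraries) exceeded the highest of these 4 lists by 0.68 there and by at most 0.09 in the other 5 libraries. That excess is no independent evidence, as it reuses the high Kupffer value that singled out this library. The neutrophil and mesothelial lists, which were not part of this test, were also raised there (0.72 each) and the monocyte-derived list too (0.30). More Kupffer cells, or higher expression in them, in that sample stay open.

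The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 0 genes past the threshold, as many or more were given by all 10, and the highest other split gave 3. At an unadjusted p below 0.05 the real split gave 2161 genes, which 1 of the 10 splits reached, itself, and the highest other gave 2098. For gene lists the real split gave 16 with the preset correlation, 2 of the 10 splits, itself included, gave as many or more, and the other splits gave 5 to 17.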
